A study of Homo sapiens with 9 samples.

How the data were processed

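RNA was measured in human osteoclasts, the multinucleated cells that resorb bone, grown from peripheral blood mononuclear cells. Per the labels' protocols, mononuclear cells of 3 donors were pooled and kept for 4 days with 50 ng/mL of M-CSF, the growth factor of the macrophage lineage. M-CSF was then lowered to 30 ng/mL and RANKL, the cytokine that drives osteoclast formation, was added at 50 ng/mL for 8 days. Vehicle or 1 of the compounds, alendronate or risedronate at 100 nM, was present in this period, and the medium was renewed every 4 days. Labelled RNA was prepared from 6 ug of total RNA per array, and each of the 3 groups has 3 arrays of the Affymetrix human U133 Plus 2.0 type. The labels call the arrays of a group biological replicates and do not say whether each came from its own pool of donors, so p-values measure the spread between these samples.

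The deposited values are intensities, 1 linear signal per probe set and array. They were made with MAS5, per the submitters' processing notes, and its version is not given in the sources used here. In the deposited table the mean without the highest and lowest 2% of values was 500 on each of the 9 arrays, so the scaling of the authors was kept. Median signals lay between 104 and 129. The table used here holds no detection calls, so a low signal cannot be separated from background. The ratio of 3' to 5' control signals lay between 0.95 and 1.11 for GAPDH and between 1.11 and 1.38 for ACTB, and no pair of arrays held identical values. The number of arrays limits the precision.

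Of 54675 probe sets, 62 controls and 95 of XIST or Y-linked genes were left out. In the platform annotation 41097 probe sets have 1 gene symbol, 1801 have several and 11777 have none. Symbols were updated through gene identifiers from a table of the GRCh38.p14 assembly, used for names alone, which matched 41043 of the probe sets with 1 symbol. No gene was named from a probe set with several symbols. Signals were used as log2(signal + 1), a scale that understates changes of low signals. A probe set was kept if it lay above the median of its array on at least 3 of the 9 arrays, and each gene was represented by its kept probe set of highest mean, which gave 13905 genes.

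limma 3.58.1 in R 4.3.3 was fitted to the 9 arrays with 3 group means and an intensity trend in eBayes. The comparisons were alendronate with vehicle, risedronate with vehicle, risedronate with alendronate, and the mean of both compounds with vehicle. p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are log2 differences with their standard error (SE) or 95% confidence interval, and signals are means with SD over 3 arrays. The 35 gene lists, with 750 genes, were fixed before the data were examined, as were the tests, most of the alternative settings and the rule for naming genes. Of the list genes 632 were tested, and 66 without a named probe set were not analysed here. Lists were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists within a comparison, and tested again with an estimated correlation.

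The rule named, for each of the 3 comparisons between groups, the 8 genes of largest change in each direction among called genes whose arrays did not overlap, filled up with the genes of smallest p. It added up to 4 members of smallest p from each list described, and a fixed set of genes of the mevalonate pathway and of osteoclasts. Unnamed loci were left out. Single HLA genes were also left out, a choice made after their values were seen, because their levels can reflect donors. Genes printed outside the rule are marked where they appear.

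Replicate numbers are shared between the groups. Deviations of arrays from their group means correlated at 0.15 to 0.78 across genes in all 9 pairs with the same number in different groups, and at -0.62 to 0.19 in the other 18 pairs. By these deviations all 9 arrays correlated best, among arrays of the other groups, with those of their own number. The numbers thus pair the samples, as read from the values and not from the labels. In log2 values alendronate 2 correlated at 0.929 with alendronate 3, against 0.926 with vehicle 2 and 0.915 with risedronate 2. The design fixed beforehand has no block, and the fit with replicate number as a block is given where it changes a call.

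Alternatives covered the offset, the normalization, the filter, the choice of probe set, the variance model, the samples in the fit, the block, the thresholds and each array left out in turn. After the data were seen, 3 more were added, which left out alendronate replicate 2 with the block, the 3 arrays numbered 3, or both of these sets. The last leaves alendronate 1 as the only array of its group. The procedure was tested on simulated data for alendronate against vehicle with 13905 genes. Without the block it recovered 9.0% of genes changed 2-fold, 54.8% at 4-fold and 80.2% at 8-fold, and with the block 39.7%, 76.0% and 90%. For risedronate against vehicle, simulated list shifts of 0.5 on the log2 scale were recovered in 17 of 20 cases without the block. These simulations used the preset correlation and genes drawn independently. The list test with an estimated correlation was not simulated. T cell markers in the arrays numbered 3 did not pass it (camera adjusted p = 0.368), at a median log2 difference of 3.22. A list that fails it is therefore not shown to be unchanged.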

Results

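Gene expression was measured on 9 arrays, 3 from osteoclast cultures given vehicle, 3 from cultures given 100 nM alendronate and 3 from cultures given 100 nM risedronate. Both compounds are nitrogen-containing bisphosphonates, drugs against bone loss that inhibit farnesyl diphosphate synthase, the product of FDPS in the mevalonate pathway. Alendronate carries a primary amine on its side chain and risedronate a pyridinyl ring. The cultures expressed osteoclast genes at high signal in every group. In vehicle cultures the signal was 29234 ± 3346 (SD, n = 3) for MMP9, 19319 ± 7333 for CTSK, which encodes the bone-degrading protease cathepsin K, and 9856 ± 1872 for DCSTAMP, which is needed for cell fusion. The median signal of an array lay between 104 and 129.

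Replicate numbers separated the arrays more than treatment did. The first principal component held 48.5% of the variance and separated the arrays numbered 3 from the others. Those 3 cultures had high lymphocyte transcripts whatever the treatment. CD2, a T cell surface gene chosen after its values were seen, read 6690 in vehicle 3, 6627 in alendronate 3 and 5193 in risedronate 3, against 122.6 to 306.5 on the arrays numbered 1 and on vehicle 2 and risedronate 2. Alendronate 2 stood between them at 3118.

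**Figure D1:**
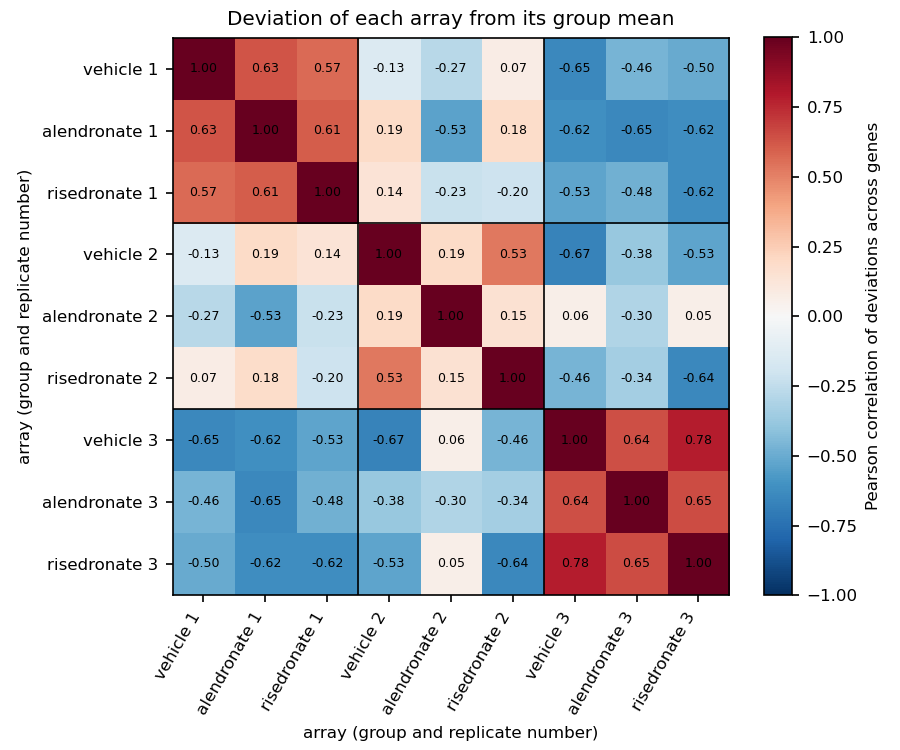
Pearson correlation across 13905 genes between the deviations of each pair of arrays from their group means, with arrays ordered by replicate number on both axes and the colour scale running from -1 to 1. Arrays that share a number correlate at 0.15 to 0.78 across groups, and arrays within a group are pushed below 0 by the subtraction of their own mean.

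Alendronate was compared with vehicle to ask what the compound changes in differentiating osteoclasts. No gene passed the test. CAV3, which encodes the muscle membrane protein caveolin 3, had the lowest p. Its signal was 52.4 ± 3.3 (SD, n = 3) with vehicle and 242 ± 80 with alendronate, a log2 fold change of 2.14 ± 0.31 (SE, adjusted p = 0.891). The vehicle signal lies below the array medians, and a single probe set represents the gene. MMP3, a matrix metalloproteinase, had 2.96 ± 0.88 and FAM3D 1.56 ± 0.47, and FCAR, an Fc receptor for IgA, had 1.22 ± 0.41. On the lower side GPM6A had -2.43 ± 0.49, RENBP -1.75 ± 0.39 and PHYHIPL -1.13 ± 0.27. None of these passed. NRSN2, HIPK4, LCNL1 and DCC completed the 8 genes on the higher side, with log2 fold changes of 1.85 to 1.99. LINC00598, BTNL9, ZNF414, OR5P3 and TNFRSF10A-DT completed the lower side, with -2.15 to -1.36, and most of these genes had signals near or below the array medians in 1 of the groups.

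Genes of the target pathway and of osteoclast function did not pass either. FDPS had a log2 fold change of 0.26 with a 95% confidence interval of -0.41 to 0.93, and SQLE had 0.38 (-0.43 to 1.18). GGPS1, HMGCS1 and IDI1, enzymes of isoprenoid and sterol synthesis, had 0.029, 0.31 and 0.12. CTSK had 0.17 (-0.71 to 1.05) and MMP9 0.017 (-0.29 to 0.32). CALCR, ITGB3, DCSTAMP, NFATC1 and TNFRSF11A, which serve osteoclast identity, adhesion, fusion and RANK signalling, had 0.28, 0.55, 0.089, 0.19 and 0.0033. Of 28 osteoclast genes 0 were called, also when adjusted over the list alone, and the list median was -0.0082 (camera adjusted p = 0.610). The list's median and its test differed in sign. Among 18 subunits of the vacuolar ATPase, the proton pump of the resorbing membrane, ATP6V0A1 had -0.23 ± 0.17 and ATP6V0D2 -0.32 ± 0.40, and the list did not pass (adjusted p = 0.752). Podosome and integrin genes (25 tested) had an adjusted p of 0.892, although PTK2B, a kinase of the actin ring, had -0.68 ± 0.27. Small GTPases and their regulators (34 tested) had an adjusted p of 0.551, with RCE1 at -0.55 ± 0.35.

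**Figure D2:**
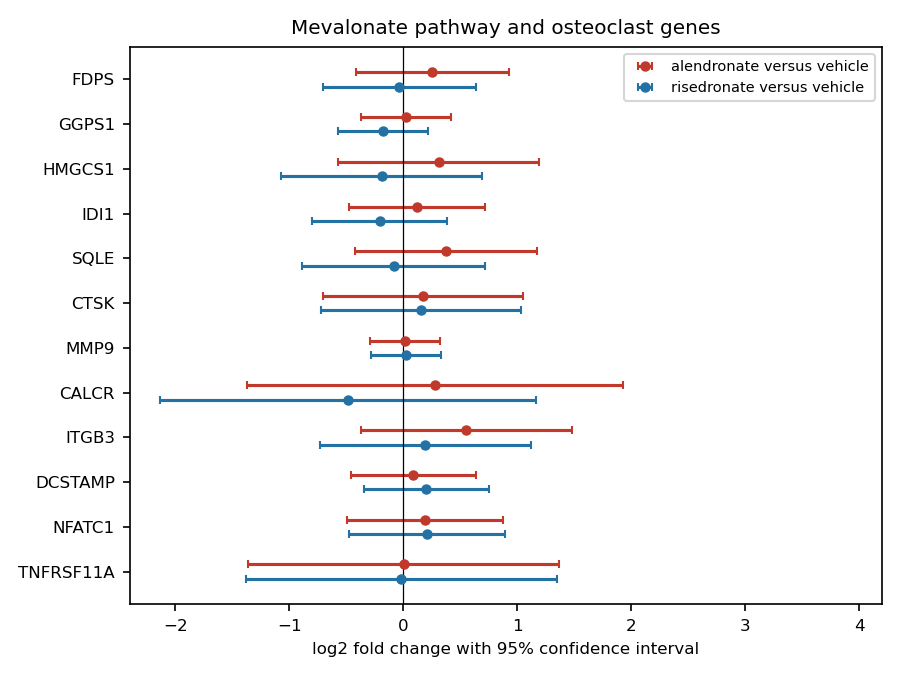
Log2 fold changes (horizontal axis) of 12 genes of the mevalonate pathway and of osteoclasts under alendronate and risedronate, each against vehicle, with points for the limma estimate and bars for its 95% confidence interval (n = 3 arrays per group). The fit has no block by replicate number. Every interval includes 0.

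Among the gene lists, 6 rose and 1 fell with alendronate. Cytokines and chemokines driven by NF-kB rose, with 23 of 25 members above 0 and a median of 0.74 (camera adjusted p = 4.1e-06). CXCL5, a neutrophil chemokine, had 2.46 ± 1.21 (SE), CXCL3 2.02 ± 1.04, CXCL2 1.32 ± 0.94 and CCL20 2.58 ± 1.87. Interferon-stimulated genes rose, with 26 of 31 members above 0 and a median of 0.52 (adjusted p = 0.00027), and USP18 had 0.82 ± 0.61, CMPK2 1.14 ± 0.93, MX2 0.54 ± 0.48 and IFIT1 0.87 ± 0.78. Gamma-delta T and NK cell markers rose with a median of 0.63 (adjusted p = 0.0497), and GZMB, a granzyme, had 1.88 ± 1.83. With an estimated correlation the adjusted p of each of these lists was 0.872. The 16 members tested of the last list are NK cell and cytotoxic genes. Alendronate 2 stood furthest above the vehicle array of its own number in these lists. Its medians over that array were 2.87 for the NF-kB list, 2.14 for the interferon list, 2.38 for T cell markers and 2.04 for gamma-delta T and NK cell markers. In alendronate 1 and 3 the same medians were -0.17 and -0.22, 0.0058 and -0.81, -0.29 and 0.090, and -0.0045 and 0.027. IL1B, chosen after its values were seen, read 15151 in alendronate 2 and 515 to 2381 on the other arrays. Without alendronate 2 the median was 0.15 for the NF-kB list (adjusted p = 0.495) and -0.27 for the interferon list (0.068). With the replicate block in that fit the interferon list fell, at -0.40 (adjusted p = 3.9e-09, and adjusted p = 0.680 with an estimated correlation). For gamma-delta T and NK markers it was 0.66 (0.141), no smaller than before, in a fit that sets alendronate 1 and 3 against vehicle 1, 2 and 3. With the block it was 0.11 (0.662), and without alendronate 3 instead, in the fit with no block, it was -0.23.

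Genes of glycolysis and the hypoxia response rose with alendronate, with 23 of 24 members above 0 and a median of 0.18 (camera adjusted p = 0.012). PFKFB3 had 0.42 ± 0.32 (SE), PFKP 0.66 ± 0.71, ALDOC 0.43 ± 0.51 and TPI1 0.25 ± 0.30. Targets of p53 fell, with 16 of 17 members below 0 and a median of -0.29 (adjusted p = 0.0455), and GDF15, a stress cytokine, had -0.83 ± 0.66, BAX -0.39 ± 0.28, POLH -0.33 ± 0.26 and DDB2 -0.42 ± 0.34. NRF2 targets and metallothioneins rose (median 0.16, adjusted p = 0.0455), with SRXN1 at 0.50 ± 0.28 and SLC7A11, a cystine transporter, at 0.95 ± 0.71. Metalloproteinases and their inhibitors also passed (adjusted p = 0.0455) with a median of 0.017, and MMP12 had 1.05 ± 0.47, MMP7 0.71 ± 0.60 and MMP14 -0.27 ± 0.20. For these 4 lists alendronate 2 gave medians of 0.38, -0.49, 0.91 and 0.29 against its vehicle, while its T cell markers stood at 2.38. With an estimated correlation the adjusted p was 0.872 for each. Without alendronate 2 the medians of glycolysis genes and p53 targets stayed at 0.20 (adjusted p = 0.057) and -0.24 (0.131), so their calls ended with little change in size. NRF2 targets and metalloproteinases went to -0.043 (0.843) and -0.030 (0.746). With the replicate block and alendronate 2 left out, the medians were 0.037 for glycolysis genes (0.369) and -0.092 for p53 targets (adjusted p = 0.033, and adjusted p = 0.686 with an estimated correlation). NRF2 targets then fell, at -0.22 (adjusted p = 0.0011, and adjusted p = 0.680 with an estimated correlation).

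**Figure D3:**
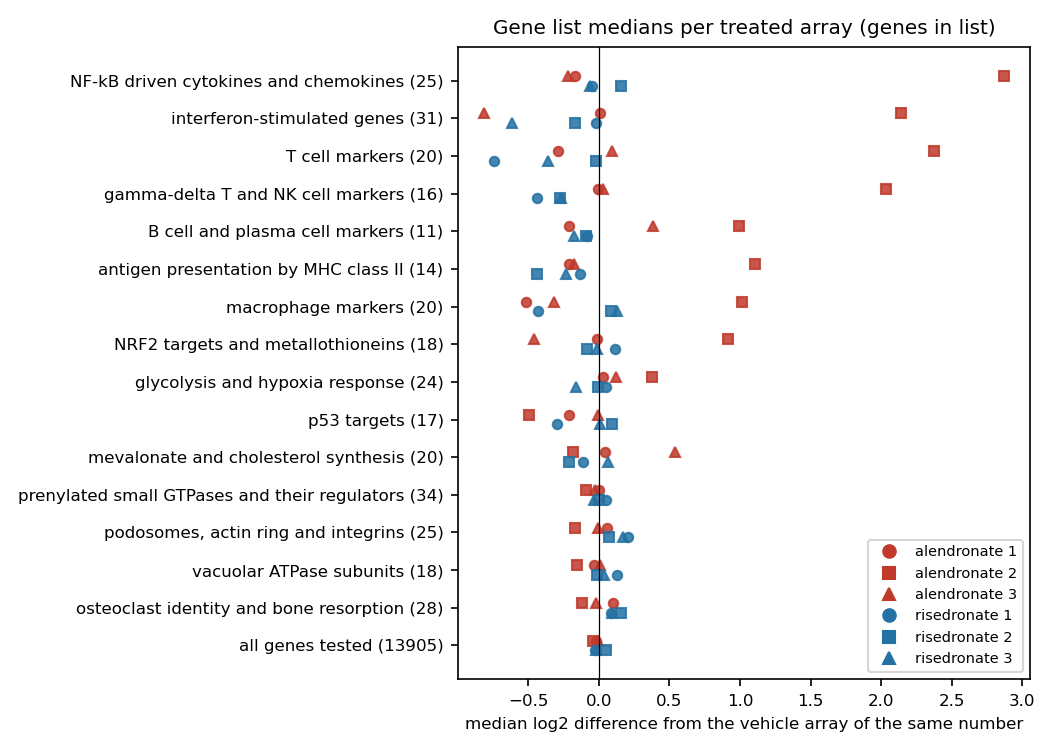
Median log2 difference of the members of 15 gene lists and of all genes tested (vertical axis, with the number of genes) between each of the 6 treated arrays and the vehicle array of the same number (horizontal axis). Alendronate 2 lies at 2.87 for the NF-kB list, 2.14 for interferon-stimulated genes and 2.38 for T cell markers, and its median over all genes is -0.045.

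In the test of alendronate against vehicle, limma called 0 of 13905 genes, with 129 at an unadjusted p under 0.05. Arrays that are not paired by number would give 695. Unchanged groups simulated with the replicate numbers kept gave 184 ± 13 (SD of 100 simulations). The block also called 0, with 430 at an unadjusted p under 0.05. The arrays of both groups did not overlap in 3.7% of genes, where arrays not paired by number would give 10%. No member of any list was called over all genes tested or adjusted over the list alone. Of the 7 list calls 0 held with an estimated correlation, and 1 list was called without alendronate 2, that of mevalonate and cholesterol synthesis (median 0.23, adjusted p = 0.046, and adjusted p = 0.920 with an estimated correlation), which had an adjusted p of 0.062 with all arrays. Other arrays moved the count as well, to 4 without vehicle 1, 2 without vehicle 2, 15 without vehicle 3, 11 without alendronate 1, 4 without alendronate 3 and 4 without risedronate 2. With the replicate block 9 lists were called. T cell markers (adjusted p = 0.00034), B and plasma cell markers (0.0039) and heat shock genes (0.0058) were added, the last with HSPD1 at 0.24 ± 0.17, and the NRF2 list was lost (0.066). With an estimated correlation 0 of these 9 lists were called, and the lowest adjusted p was 0.812. The power of that test was not simulated, so its result does not show that a list is unchanged.

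Risedronate was compared with vehicle at the same dose and time. No gene and no list passed the test. CAV3 again had the lowest p, with a signal of 304 ± 55 (SD, n = 3) against 52.4 ± 3.3 and a log2 fold change of 2.50 ± 0.31 (SE, adjusted p = 0.263). AXIN1, a scaffold of WNT signalling, had 1.62 ± 0.38, AKT1, a kinase of growth factor signalling, 0.63 ± 0.19, CAMP, which encodes an antimicrobial peptide, 1.59 ± 0.51, and MUC12-AS1 2.21 ± 0.71. KLHL35, MRNIP and LRRC37A4P had 1.05, 1.72 and 1.31. On the lower side GABRB2 had -1.67 ± 0.33, SAG -1.59 ± 0.37, ST3GAL3 -0.82 ± 0.22 and RBFOX1 -1.15 ± 0.29, and SLC6A17, ANO9, PRPH2 and ZNF787 had -1.39, -1.40, -1.48 and -1.58. KLHL35 depends on the probe set, with -0.89 when probe sets of the _x_at and _s_at kinds were left out.

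FDPS had a log2 fold change of -0.033 with risedronate (95% confidence interval -0.70 to 0.64), SQLE -0.083 (-0.88 to 0.72), HMGCS1 -0.19, IDI1 -0.21 and GGPS1 -0.17. CTSK had 0.16 (-0.72 to 1.04), MMP9 0.026 (-0.28 to 0.33), DCSTAMP 0.20, NFATC1 0.21, ITGB3 0.19, CALCR -0.48 and TNFRSF11A -0.015. SIGLEC15, a receptor in osteoclast maturation, had 0.74 ± 0.46 (SE) and CTTN, a podosome component, 0.52 ± 0.31. The camera adjusted p was 0.618 for the osteoclast list, 0.601 for mevalonate and cholesterol synthesis and 0.302 for podosome and integrin genes. Without the arrays numbered 3 the mevalonate list was lower with risedronate, at a median of -0.20 (adjusted p = 0.019, and adjusted p = 0.995 with an estimated correlation). Interferon-stimulated genes lay below 0 in 29 of 31 members, with a median of -0.31 (adjusted p = 0.302), and MHC class II genes in 12 of 14, with a median of -0.34 (0.302) and CD74, the invariant chain, at -0.43 ± 0.48. T cell markers had a median of -0.42 (0.419), with CD8B at -0.80 ± 0.76 and TRAT1 at -1.85 ± 2.00. T cell transcripts were high in number 3 of both groups, with CD2 at 6690 in vehicle and 5193 in risedronate, and alendronate 2, which enters this test through the variance alone, had a T cell marker median of 2.38 over vehicle 2. With the replicate block the T cell and MHC class II lists fell, each with an adjusted p of 0.027, and with an estimated correlation and the block each had 0.986. The block with alendronate 2 left out called 6 lists, among them interferon-stimulated genes (adjusted p = 1.8e-07, and adjusted p = 0.725 with an estimated correlation) and gamma-delta T and NK markers (adjusted p = 0.00054, and adjusted p = 0.606 with an estimated correlation), both lower with risedronate.

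limma called 0 genes for risedronate against vehicle, with 129 at an unadjusted p under 0.05, and 0 with the block, with 362. Lists called numbered 0, and 2 with the replicate block. Leaving out 1 array gave 4 lists without vehicle 1, 3 without vehicle 2, 3 without vehicle 3, 1 without risedronate 1 and 14 without risedronate 3. Separation of the groups was seen in 3.8% of genes, where arrays not paired by number would give 10%.

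Risedronate was set directly against alendronate at the matched dose of 100 nM, which tests the difference between the pyridinyl and the amine compound. No gene passed (lowest adjusted p = 0.9998). AKT1 had the lowest p, with a signal of 1146 ± 71 (SD, n = 3) with risedronate, 599 ± 50 with alendronate and 749 ± 143 with vehicle, a log2 difference of 0.94 (95% confidence interval 0.50 to 1.38). TLR9, a DNA sensor, had 1.25 ± 0.38 (SE), SCRN1 0.95 ± 0.28 and GPM6A 1.77 ± 0.49, and LINC00598, CCDC7, ZMYM3 and VWA3A had 1.87, 1.90, 1.08 and 1.33. CTRB2 had -0.92 ± 0.21, MEST, an imprinted gene, -0.89 ± 0.26, GEMIN4 -1.03 ± 0.30 and SLC6A17 -1.54 ± 0.35, and SAG, GABRB2, CIMIP2C and RBFOX1 had -1.54, -1.39, -1.51 and -1.03. ZMYM3 turned to -0.048 without probe sets of the _x_at and _s_at kinds. For target and osteoclast genes the intervals of the difference were -0.96 to 0.38 for FDPS, -1.26 to 0.34 for SQLE and -0.89 to 0.86 for CTSK. They were -0.30 to 0.32 for MMP9 and -0.43 to 0.66 for DCSTAMP. Differences of this size between the compounds were not excluded by this fit, which has no block. Over all genes tested the median SE was 0.31 without the block and 0.21 with it, and intervals with the block are not given here.

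Between the compounds 7 lists were lower with risedronate and 1 was higher. Interferon-stimulated genes were lower in 31 of 31 members (median -0.80, camera adjusted p = 3.3e-08), with USP18 at -1.09 ± 0.61 (SE), IFI44 -0.96 ± 0.67 and OAS1 -0.85 ± 0.61. NF-kB driven cytokines were lower in 23 of 25 (median -0.91, adjusted p = 1.3e-05), with CXCL5 at -2.13 ± 1.21 and TNF at -1.81 ± 1.17. T cell markers (median -1.20, adjusted p = 0.0010), with IL7R at -1.87 ± 1.40, and gamma-delta T and NK cell markers (median -1.10, 0.0023), with GZMB at -1.99 ± 1.83, were lower. MHC class II genes (median -0.46, 0.0024) and glycolysis genes (median -0.17, 0.0046), with LDHA at -0.32 ± 0.28, were lower too. Mevalonate and cholesterol synthesis genes were lower in 17 of 20 members (median -0.27, 0.0024), with INSIG1, a sterol sensor, at -0.59 ± 0.40, MSMO1 -0.67 ± 0.47 and NSDHL -0.36 ± 0.25. Targets of p53 were higher in 14 of 17 (median 0.20, 0.028), with XPC at 0.40 ± 0.24 and SESN1 at 0.49 ± 0.46. With an estimated correlation the adjusted p of each of the 8 lists was 0.737.

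Alendronate 2, with its T cell marker median of 2.38 above vehicle 2, enters each of these lists. Without it the adjusted p was 0.892 for interferon-stimulated genes (median -0.096), 0.689 for NF-kB cytokines (median -0.15) and 0.109 for p53 targets, whose median of 0.21 was no smaller than with all arrays. It was 0.00078 for mevalonate and cholesterol synthesis (median -0.40), 0.021 for MHC class II, glycolysis, and gamma-delta T and NK lists, and 0.042 for T cell markers, so 5 of the 8 lists passed in this fit. It sets alendronate 1 and 3 against risedronate 1, 2 and 3. Podosome and integrin genes passed too (0.039), with PTK2B at 0.76 ± 0.27 and PXN at 0.55 ± 0.34 over all arrays, and with an estimated correlation the lowest adjusted p of any list was 0.762. With the replicate block added, MHC class II (median -0.11, adjusted p = 0.868), glycolysis (-0.077, 0.126) and podosome genes (0.082) did not pass. T cell markers (-0.37, 0.00035), gamma-delta T and NK markers (-0.39, 0.00013), the mevalonate list (-0.39, 1.7e-06) and p53 targets (0.11, 0.028) did, and with an estimated correlation the lowest adjusted p was 0.556. Without the arrays numbered 3 the mevalonate median was -0.13 (0.118). Over the vehicle array of the same number this list had 0.54 in alendronate 3, 0.040 in alendronate 1 and -0.19 in alendronate 2. In risedronate 1, 2 and 3 it had -0.11, -0.21 and 0.065. The MHC class II median turned to 0.0018 (0.770) without risedronate 2. limma called 0 genes, with 149 at an unadjusted p under 0.05, and with the block 0 and 526. With the replicate block 14 lists were called, the same 8 and those of B and plasma cells (adjusted p = 6.8e-05), immediate early genes (0.014), metalloproteinases (0.026), and apoptosis, podosome and NRF2 genes (0.047 each). The block with an estimated correlation called 0 lists, with a lowest adjusted p of 0.490. With the block and alendronate 2 left out, the NRF2 list was instead higher with risedronate (median 0.24, adjusted p = 0.00035, and adjusted p = 0.556 with an estimated correlation). Leaving out 1 array gave 5 lists without alendronate 3, 3 without risedronate 2 and 14 without risedronate 3.

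**Figure D4:**
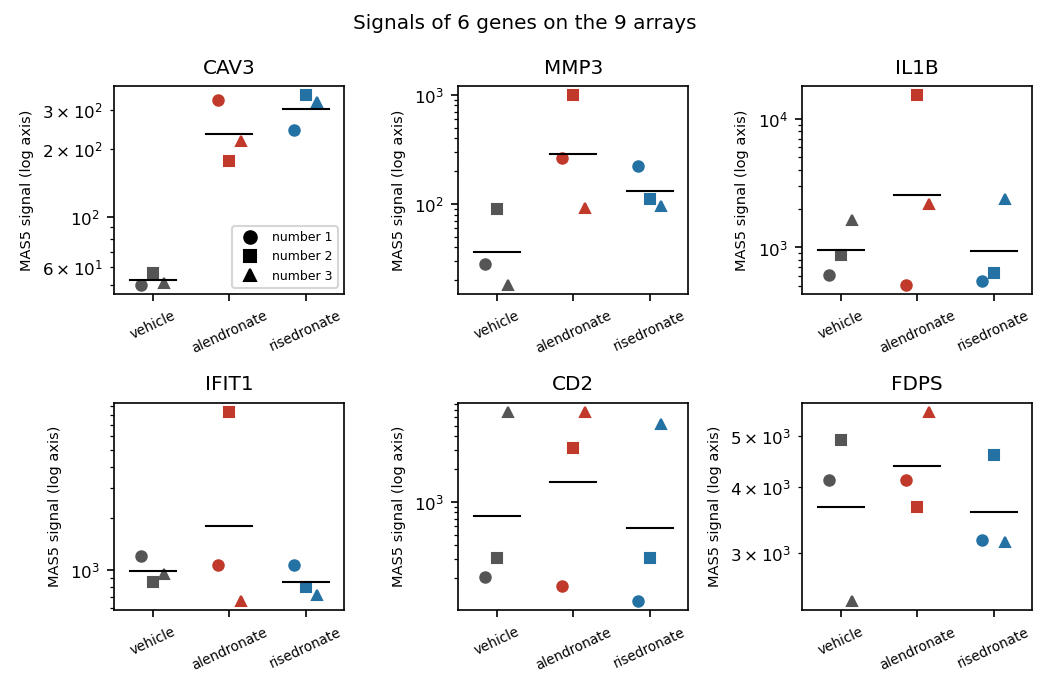
MAS5 signal on a logarithmic axis for 6 genes on the 9 arrays, with symbols for replicate numbers and lines for the geometric mean of each group. CAV3 reads 50 to 56.2 in vehicle and 177.7 to 346.9 in treated arrays, and IL1B reads 15151 in alendronate 2.

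The mean of both compounds was compared with vehicle to ask what they share. CAV3 had the lowest adjusted p (0.150) and read 332, 177.7 and 217.7 with alendronate and 242.8, 346.9 and 322.9 with risedronate, against 50, 56.2 and 51 with vehicle. The NF-kB list rose, with 20 of 25 members above 0 and a median of 0.33 (camera adjusted p = 0.035, and adjusted p = 0.955 with an estimated correlation). Its median was 2.87 in alendronate 2 and -0.22 to 0.15 in the other 5 treated arrays, and without alendronate 2 its adjusted p was 0.793. Interferon-stimulated genes then fell instead (median -0.29, adjusted p = 0.028, and adjusted p = 0.994 with an estimated correlation). Their medians over the vehicle array of the same number were -0.81 in alendronate 3 and -0.62 in risedronate 3, against 0.0058, -0.021 and -0.17 in alendronate 1, risedronate 1 and risedronate 2. limma called 0 genes, with 122 at an unadjusted p under 0.05, and 0 with the block, with 346. Leaving out vehicle 3 gave 11 lists, alendronate 1 gave 4, alendronate 3 gave 0 and risedronate 2 gave 4.

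Responses to both compounds share the vehicle arrays. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.40. Unchanged groups gave 0.50 ± 0.014 (SD of 100 simulations), drawn with the spread left after replicate numbers were fitted. Each gene was drawn independently in these groups. Their SD is therefore too small to place the observed r or covariance above or below unchanged groups. Without alendronate 2 the observed r was 0.40 against 0.45 ± 0.015. Leaving out 1 array gave r = 0.12 without risedronate 3, 0.24 without alendronate 1, 0.59 without vehicle 1 or vehicle 2 and 0.72 without vehicle 3, and no unchanged groups were simulated for these smaller sets of arrays. The covariance was 0.044 against a simulated 0.062 ± 0.0024, and 0.046 against 0.048 ± 0.0025 without alendronate 2, and the sign was shared by 62.6% of genes against 66.6%. No gene was called in both. At an unadjusted p under 0.05, 7 genes were higher and 15 lower in both. Unchanged groups with the replicate numbers kept gave 20 ± 3.9 and 21 ± 4.4, a simulation added after the overlap was seen. The simulated comparisons had 184 ± 13 and 187 ± 13 genes at that p, against 129 observed in each. The 3 vehicle arrays cannot be split into 2 sets of at least 2 arrays.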

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

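The tests of explanations in this part were chosen after the results were seen, while the direct comparison of the compounds was planned.

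The direct test between the compounds, risedronate minus alendronate, passed its threshold for 8 gene lists (camera adjusted p with the preset correlation). These were interferon-stimulated genes (3.3e-08), NF-kB cytokines (1.3e-05), T cell markers (0.0010), gamma-delta T and NK cell markers (0.0023), mevalonate and cholesterol synthesis (0.0024), MHC class II (0.0024), glycolysis and hypoxia (0.0046) and p53 targets (0.028). None of them passed with an estimated correlation, where the adjusted p of each was 0.737. Other splits of the 6 arrays are too few to test chance: 8 of 10 gave as many lists, the real count was 8 and the highest other 16. The same holds for alendronate against vehicle, where 7 of 10 splits gave as many lists (real 7, highest other 15). A real count of 0 is matched by every split and tests nothing: this covers the lists of risedronate against vehicle (10 of 10, highest other 17), the genes of all 3 comparisons (10 of 10, highest other 0) and, fitted as 2 groups, the genes and lists of both compounds against vehicle (84 of 84). In the last of these the highest other splits gave 2792 genes and 18 lists. The gene count came from the split that sets the 3 arrays numbered 3 apart, which points to the structure by replicate number. That split gave 17 lists, and the 18 lists came from splits that mix the numbers. Among the 27 splits that part the numbers the highest were 0 genes and 14 lists.

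Alendronate 2 carried high NF-kB and interferon lists. A response to alendronate shared by the 3 cultures is argued against by alendronate 1 and 3, whose highest median of both lists over their own vehicle was 0.0058. The NF-kB list stood 1.12 higher in the arrays numbered 3 than in the others (median log2 difference), which could hide a smaller rise in alendronate 3. For that list the argument rests mainly on alendronate 1. For these lists, mixing with RNA of the cultures numbered 3 is argued against by 28 of 56 members that lay at least 2-fold above the highest of the other 8 arrays, against 3 for the next array. For the T and NK cell lists such mixing stays open. There, 30 members were over 4-fold higher in the arrays numbered 3 than in vehicle 2 and risedronate 2. Alendronate 2 stood at a median fraction of 0.38 of that difference in signal, with a range of 0.086 to 2.29 over these 30 members. A larger share of lymphocytes alone is argued against for those 28 members. They also lay above the arrays numbered 3, where CD2 read 5193 to 6690 against 3118 in alendronate 2. For the interferon list as a whole the test left it open. That list had a median of 1.03 in alendronate 2 above vehicle 3, with quartiles of -0.032 and 1.68. For the T and NK cell lists, more lymphocytes in this culture stays open, with 8 of 11 B and plasma cell members higher than in vehicle 2, and so does expansion of gamma-delta T cells by the compounds, since the members tested are NK cell and cytotoxic genes, whose highest median was -0.0045 in alendronate 1, risedronate 1 and risedronate 2. The latter 2 tests took the place of first forms whose values had been seen.

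CAV3 was higher in 6 of 6 treated arrays than in the vehicle arrays. Treated and vehicle arrays did not overlap in 113 of 13905 genes, or 0.81%, where arrays not paired by number would give 2.4%. Of 84 splits of the arrays, 6 gave a lowest adjusted p as small as the real 0.079 of the fit with 2 groups, the lowest other being 3.1e-05, so over all splits chance cannot be excluded. The other 5 do not part the replicate numbers, and among the 27 splits that do, only the real one gave such a value, 1 of 27, the next being 0.860. A background signal in vehicle could not be tested without detection calls, and no biological explanation was tested.

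The mevalonate list was higher with alendronate once alendronate 2 was left out. A response shared by both compounds and the cultures is argued against by list medians over 0.1 in only 1 of the 5 other treated arrays, alendronate 3 at 0.54. A low vehicle 3 as the whole cause stays open. Risedronate 3 had a median of 0.065 over it, but a single array cannot decide this. Risedronate 1 and 2 had -0.11 and -0.21 over their own vehicle. Vehicle 3 had the lowest signal of any array for FDPS (2434), HMGCS1 (586) and SQLE (1662). With vehicle 3 alone left out, alendronate gave -0.039 for FDPS, -0.078 for HMGCS1 and -0.062 for SQLE. IDI1 then had -0.077 and MSMO1 -0.12, while GGPS1 stayed above 0, at 0.15. A response to alendronate in the culture of alendronate 3, which a single array cannot test, stays open too.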

How the results depend on the processing

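The alternatives that left out alendronate 2 with the block, the arrays numbered 3, or both were chosen after the data were seen, and the others were planned. No gene was called in any comparison under any of the alternatives that keep the adjusted threshold, the looser adjusted p under 0.10 included. At an unadjusted p under 0.05, limma gave 129 genes for alendronate, 129 for risedronate, 149 between the compounds and 122 for both compounds against vehicle. Low signal over background limits many named genes, and the leave-one-out fits rest on fewer arrays. The cause of the changes below was not tested.

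List counts are given as main value and alternative. For alendronate the 7 lists became 4 with quantile normalization, 4 with median centring, 3 with no filter, 3 without probe sets of the _x_at and _s_at kinds, 11 with the block and alendronate 2 left out, 12 with the arrays numbered 3 left out and 0 with an estimated correlation. With both sets left out, the arrays numbered 3 and alendronate 2, alendronate 1 is alone in its group. No count is given there for comparisons with alendronate. For risedronate the 0 lists became 2 with the filter at the 70th percentile, 1 with only the groups compared, 2 with the replicate block, 6 with the block and alendronate 2 left out, 2 without the arrays numbered 3 and 3 with both sets left out. Between the compounds the 8 lists became 13 with the filter at the 70th percentile, 14 with the replicate block, 16 without the arrays numbered 3 and 0 with an estimated correlation. For both compounds the 1 list became 0 with quantile normalization, median centring, the filter at the 70th percentile, no probe sets of the _x_at and _s_at kinds, only the groups compared or an estimated correlation, and 7 with the block and alendronate 2 left out or without the arrays numbered 3. Leaving out 1 array gave 1 to 15 lists for alendronate, 0 to 14 for risedronate, 3 to 14 between the compounds and 0 to 11 for both. The replicate block changed no call of a gene, and its changes to list calls are given beside each comparison.

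List medians, or the direction of their tests, changed in these fits. With the block and alendronate 2 left out, alendronate gave -0.18 for NF-kB cytokines, -0.40 for interferon-stimulated genes and -0.22 for NRF2 targets, the compounds differed by 0.039 for NF-kB cytokines and 0.095 for interferon-stimulated genes, and both compounds gave -0.078 for NF-kB cytokines. Without the arrays numbered 3 and alendronate 2, alendronate 1 is the only array of its group, so these values are effect sizes alone. Alendronate then gave -0.19 for NF-kB cytokines and -0.17 for interferon-stimulated genes. NRF2 targets had 0.18 and gamma-delta T and NK markers 0.0057, where the median kept its sign and the direction of the test turned in both. The compounds then differed by 0.19 for NF-kB cytokines and 0.054 for interferon-stimulated genes, and both gave -0.042 for NF-kB cytokines. Leaving out 1 array, alendronate medians ranged from -0.23 to 1.89 for gamma-delta T and NK markers, from -0.27 to 1.04 for interferon-stimulated genes and from -0.043 to 0.36 for NRF2 targets, and the MHC class II difference from -0.74 to 0.0018. The correlation of both responses ranged from 0.12 to 0.72.

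Named genes, none of which was called in any fit, changed sign in 76 of the values from whole alternatives and 73 from single arrays left out, and 3365 and 1925 values kept their sign. MMP9 had -0.014 in alendronate versus vehicle with quantile normalization. TNFRSF11A had 0.0022 in risedronate versus vehicle with quantile normalization. CTSK had 0.014 in risedronate versus alendronate with quantile normalization. MMP9 had -0.0017 in risedronate versus alendronate with median centring. GGPS1 had -0.049, IDI1 -0.12 and TNFRSF11A -0.18 in alendronate versus vehicle with the mean of a gene's probe sets. ITGB3 had -0.18 and ATP6V1D -0.0089 in risedronate versus vehicle with the mean of a gene's probe sets. NFATC1 had -0.087, TNFRSF11A 0.12, SRC -0.094, PXN -0.19 and PGD 0.062 in risedronate versus alendronate with the mean of a gene's probe sets. GGPS1 had -0.13 and IDI1 -0.58 in alendronate versus vehicle with no probe sets of the _x_at or _s_at kind. KLHL35 had -0.89, ITGB3 -0.19 and ATP6V0A2 0.20 in risedronate versus vehicle with no probe sets of the _x_at or _s_at kind. ZMYM3 had -0.048, GGPS1 0.042 and NFATC1 -0.27 in risedronate versus alendronate with no probe sets of the _x_at or _s_at kind. TNFRSF11A had -0.29 in alendronate versus vehicle with array weights. CTSK had 0.069 and TNFRSF11A 0.21 in risedronate versus alendronate with array weights. GGPS1 had -0.012, RAB3D 0.16, CXCL2 -0.32, CMPK2 -0.34, MX2 -0.078, IFIT1 -0.31, GCLM -0.14, IL7R -0.51, CST7 -0.22 and VPREB3 0.20 in alendronate versus vehicle with the block and alendronate 2 left out. ITGB3 had 0.079, DCSTAMP -0.074, CXCL5 0.0053, CXCL2 0.039, CXCL3 0.15, SLC7A11 0.19, GCLM 0.19, PGD 0.026 and IER3 0.011 in risedronate versus alendronate with the block and alendronate 2 left out. FDPS had -0.21, IDI1 -0.078, DCSTAMP -0.074, TNFRSF11A -0.16 and MSMO1 -0.048 in alendronate versus vehicle with the arrays numbered 3 left out. CALCR had 0.18 in risedronate versus vehicle with the arrays numbered 3 left out. CTSK had 0.10 and TNFRSF11A 0.033 in risedronate versus alendronate with the arrays numbered 3 left out. FDPS had -0.13, CTSK -0.099, ITGAV -0.15, ATP6V0D2 0.037, MSMO1 -0.081, RAB3D 0.050, RAB5A 0.083, CCL20 -0.30, MX2 -0.11, DDB2 0.057, HSPD1 -0.10, HSPE1 -0.064, HSPB1 -0.15, CD27 -0.016, IL7R -0.82, JCHAIN -0.49 and IGHM -0.39 in alendronate versus vehicle with the arrays numbered 3 and alendronate 2 left out. CALCR had 0.18 in risedronate versus vehicle with the arrays numbered 3 and alendronate 2 left out. CTSK had 0.23, DCSTAMP -0.11, NFATC1 -0.090, RRM2B -0.010, IER3 0.039 and IL7R 0.082 in risedronate versus alendronate with the arrays numbered 3 and alendronate 2 left out.

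With 1 array left out at a time, the following log2 fold changes crossed 0. ATP6V0D2 ranged from -0.63 to 0.047, CD4 from -0.53 to 0.069, CTSK from -0.20 to 0.40, DCSTAMP from -0.076 to 0.32 and DNAJB4 from -0.12 to 0.93 in alendronate versus vehicle. FDPS ranged from -0.039 to 0.47, GCLM from -0.0029 to 0.51, GGPS1 from -0.033 to 0.15, HMGCS1 from -0.078 to 0.61 and HSPB1 from -0.10 to 0.68 in alendronate versus vehicle. IDI1 ranged from -0.077 to 0.22, IFIT1 from -0.23 to 1.59, ITGAV from -0.013 to 0.68, MMP9 from -0.038 to 0.11 and MSMO1 from -0.12 to 0.78 in alendronate versus vehicle. MX2 ranged from -0.10 to 0.94, NFATC1 from -0.13 to 0.43, RAB3D from -0.65 to 0.0028, SQLE from -0.062 to 0.63 and TNFRSF11A from -0.50 to 0.42 in alendronate versus vehicle. VPREB3 ranged from -1.46 to 0.044 in alendronate versus vehicle. ATP6V1D ranged from -0.080 to 0.39, CD7 from -2.41 to 0.32, CD74 from -0.84 to 0.076, CD8A from -2.76 to 0.046 and CTSK from -0.21 to 0.50 in risedronate versus vehicle. FDPS ranged from -0.33 to 0.18, HMGCS1 from -0.58 to 0.11, MMP9 from -0.041 to 0.13, NFATC1 from -0.11 to 0.44 and SQLE from -0.52 to 0.17 in risedronate versus vehicle. TNFRSF11A ranged from -0.51 to 0.40 in risedronate versus vehicle. BANK1 ranged from -1.70 to 0.20, CD79A from -0.67 to 0.043, CTSK from -0.24 to 0.33, DCSTAMP from -0.12 to 0.28 and GCLM from -0.46 to 0.052 in risedronate versus alendronate. ITGB3 ranged from -0.78 to 0.16, MMP9 from -0.058 to 0.11, NFATC1 from -0.16 to 0.18, PAX5 from -1.50 to 0.097 and PGD from -0.32 to 0.060 in risedronate versus alendronate. SLC7A11 ranged from -1.18 to 0.14 and TNFRSF11A from -0.52 to 0.48 in risedronate versus alendronate.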

Other observations

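The tests in this part were chosen after the results were seen, and the comparison of replicate numbers was made after their correlation was found.

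Replicate numbers differed in 3996 of 13905 genes at an adjusted p under 0.05 (limma, over the 3 numbers with treatment in the fit). The 3 arrays of a number are paired and are not independent replicates of it. The p-values of this comparison measure the spread between arrays of a number, and not the spread between numbers, of which there are 3. Between the arrays numbered 3 and the rest, 1852 genes were higher and 1707 lower. T cell markers rose in the arrays numbered 3 (median 3.22 on the log2 scale, 17 of 20 members called, camera adjusted p = 2.8e-10), as did gamma-delta T and NK cell markers (3.43, 14 of 16, 6.3e-09) and B and plasma cell markers (2.80, 9 of 11, 1.8e-05). Genes of the unfolded protein response and ATF4 rose too (median 1.01, 18 of 25 called, 6.3e-09), as did glycolysis and hypoxia genes (0.93, 17 of 24, 6.3e-09) and immediate early genes (1.14, 9 of 14, 3.3e-05). Osteoclast genes fell (median -0.27, 8 lower and 3 higher of 28, adjusted p = 0.019), as did vacuolar ATPase subunits (-0.27, 8 of 18 lower, 0.00072) and oxidative phosphorylation (-0.26, 9 of 27 lower, 0.00091). With an estimated correlation the adjusted p of these lists was 0.325 to 0.548. CTSK, named by the rule, read 10949 to 14999 on these arrays and 21917 to 27199 on the others.

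A hypothesis, found with alendronate 2 left out, is that either compound lowers MHC class II transcripts. Their median lay below the vehicle array of the same number in 5 of 5 treated arrays other than alendronate 2, with values of -0.21 and -0.18 for alendronate 1 and 3, and -0.13, -0.44 and -0.23 for risedronate 1, 2 and 3. Alendronate 2 went the other way, at 1.11. Without it, the 2-sided exact permutation p within replicate numbers was 0.0556, the smallest that the 18 arrangements can give, so that test could not pass 0.05. The list was picked from 35 after the values were seen, and this p is not adjusted for that choice. In the same 5 arrays the medians of immediate early genes also all lay below 0 (-0.33 to -0.047). Those of LXR targets and cholesterol efflux all lay above 0 (0.0077 to 0.41). For both compounds against vehicle, with the replicate block and alendronate 2 left out, the list median was -0.29 (camera adjusted p = 2.8e-05, and adjusted p = 0.741 with an estimated correlation), without the block it was -0.080 (0.944), and with all arrays and no block -0.13 (0.752). In the blocked fit without alendronate 2, interferon-stimulated genes (-0.37, adjusted p = 2.2e-10) and T cell markers (-0.16, 0.0081) fell as well, each with an adjusted p of 0.741 with an estimated correlation. Macrophage markers had -0.32 (0.069), and a change in the mix of cells is not excluded.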
